A study of Mus musculus with 24 samples.

How the data were processed

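Gene expression was measured on 24 single-colour arrays in 2 cell types sorted by flow cytometry from the tibialis anterior muscle of mice before and after injury with cardiotoxin, a venom toxin that lyses muscle fibres. Satellite cells, the stem cells of skeletal muscle, were sorted as CD45 negative, Sca1 negative, CD31 negative and alpha7-integrin positive cells with positive or low CD34. Endothelial cells were sorted as CD45 negative cells positive for Sca1, CD34 and CD31. RNA was amplified from picogram amounts before labelling with biotin. Each cell type was sampled on day 0 (uninjured) and on days 2, 4 and 8 after injury, with 3 biological replicates in each of the 8 groups.

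The deposited table holds log2 values made by the authors with RMA (background correction, quantile normalization across arrays and a summary per probe set), for which no version is given. It holds 24479 probe sets, each named by a gene identifier, and its values run from 1.29 to 12.9. Array medians lie between 4.11 and 4.40, and the arrays' 75th percentiles between 5.89 and 6.21. The number of arrays limits the precision of every value.

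Gene symbols came from the annotation table of the array, which names 23281 of the probe sets. For 23156 of these the symbol equals that of the same gene identifier in a reference gene table, and 125 identifiers are absent from that table. The other 1198 probe sets carry no symbol and were not analysed here, and Ly6a (the gene of Sca1), Lyz2 and Gapdh are not named here. No genome build is stated, so no coordinates are given.

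Samples were grouped by their titles, which match the source name in all 24 samples. The separate cell type field differs from the title in 12 samples and the time point field in 18, and both match in 2. These fields were not used, and the levels of Pax7, Pecam1, Cdh5 and Itga7 were checked against the titles in every group. Pecam1, Cdh5 and Itga7 separated the cell types on each day, while Pax7 overlapped between them on day 2. These genes bear on the cell type and cannot test the day given in the titles. Array numbers follow the order of the days, so array order and day cannot be told apart. The replicate numbers of the 2 cell types were checked as possible pairs. Of the 12 same-number pairs of one day, 4 had a correlation of group-centred values over 0.1, with a range from -0.06 to 0.20. For 13 of the 24 arrays the best correlated array of another group had the same replicate number. A shared preparation is therefore not excluded. The correlations were low, and no pairing was used in the main fit.

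The choices described here were made before the data were examined, except where the text says otherwise. A probe set entered the tests if its value lay above its array's median on at least 3 arrays, and where 2 probe sets shared a symbol the brighter was used, which left 14064 genes. All 24 arrays were fitted together in limma 3.58.1 (R 4.3.3) with 1 mean per group, 16 residual degrees of freedom and eBayes moderation. The tests were limma's moderated tests, two-sided and adjusted by Benjamini-Hochberg over all genes tested within a comparison. A gene was called at an adjusted p under 0.05 with an absolute log2 difference of at least 1, and only called genes are said to rise, fall or change. Comparisons were each later day against day 0 within a cell type, satellite against endothelial cells on each day, and the difference between the cell types in their response on each day, which is an interaction contrast. A moderated F-test over the 3 later days counted genes with any change over time in each cell type. Values are log2 differences with the standard error (SE) of the fit, and group levels are means ± SD over 3 arrays. Folds are given only where the lower group mean lies at least 1 above the array medians, since values nearer background can understate a rise or a fall.

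Fixed gene lists numbered 23. They cover sorting markers, satellite cell quiescence, myogenic differentiation, cell cycle, ribosome biogenesis, oxidative phosphorylation, glycolysis, fatty acid handling, endothelial identity, sprouting and tip cells, secreted growth and angiogenic factors, the Notch pathway, inflammatory response, interferon response, extracellular matrix and immediate early genes. They also cover markers of macrophages and other leukocytes, fibro-adipogenic progenitors, pericytes and smooth muscle, Schwann cells, mature myofibres, lymphatic endothelium and erythroid cells. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. It was tested again with an estimated correlation and with fry. Counts of called members are given over all genes tested and adjusted over the list alone.

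Named genes followed a fixed rule. In each comparison with day 0 they were the 5 called genes with the largest rise and the 5 with the largest fall for which all 3 arrays of one group lay beyond all 3 of the other, which chance gives for 10% of genes. In satellite against endothelial cells on day 0 the number was 10 in each direction under the same condition, and in each interaction the 4 called genes with the largest difference in each direction. Symbols of set placeholder patterns were left out of these, such as Gm before a digit, an ending in Rik, or BC, AI, AU or AW before digits. AA467197 matches none of the patterns and was kept. For each list the rule took up to 4 called members with the largest change. Pax7, Myod1, Myog, Mki67, Pecam1, Cdh5, Kdr, Itga7, Cd34 and Ptprc were always taken.

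The alternatives tried were array weights, centring each array on its median, quantile normalization within each cell type, no filter and a stricter filter on dim probe sets, the mean of a gene's probe sets, eBayes with trend and robust settings, no minimum log2 difference, only the 12 arrays of a cell type, a block by replicate number, a random block by the number in the array names, and leaving out each array in turn. Leaving out the 3 satellite cell arrays of day 2 was added after the data had been seen. Where an array was left out, the remaining 2 of its group were assumed to vary like the other groups. The calls were also tested on simulated data: in the day 2 satellite comparison, 72% of genes given a log2 difference of 1.5 and 100% of those given 4 were called, with 6 false calls among 13864 unchanged genes. For the difference of the day 8 responses these shares were 40% and 96%, with 9 false calls. The simulated noise was independent between genes and had 1 SD per gene in all groups. The arrays differ from this: Pecam1 had an SD of 1.10 in satellite cells and 0.09 in endothelial cells on day 2. The shares may therefore not carry over to the real comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.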

Results

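The arrays compared muscle stem cells and endothelial cells sorted from the same kind of regenerating muscle, to follow how the transcripts of each cell type change as the muscle degenerates and is rebuilt. The 24 arrays fall into 8 groups of 3: satellite cells and endothelial cells from uninjured muscle (day 0) and from muscle 2, 4 and 8 days after injury. The first principal component held 30.9% of the variance and the second 21.6%. Arrays of the same group correlated at 0.863 to 0.957, and arrays of different groups at 0.645 to 0.949.

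Before injury the sorted populations carried the transcripts of their cell types. Pax7, the transcription factor that marks satellite cells, was at 9.28 ± 0.52 (mean ± SD, log2, n = 3) in satellite cells and 4.90 ± 0.04 in endothelial cells. Pecam1, which encodes CD31, was at 7.71 ± 0.51 and 11.43 ± 0.08 in the same order, and Cdh5, which encodes VE-cadherin, at 8.05 ± 0.16 and 11.76 ± 0.07. Itga7, the alpha7-integrin gene used in the sort, was at 8.36 ± 0.60 and 5.81 ± 0.23. Ptprc, which encodes CD45 and marks the leukocytes that both sorts excluded, was at 2.97 ± 0.16 and 2.84 ± 0.06. After injury Ptprc reached 9.17 ± 1.01 in satellite cells on day 2, 6.20 ± 1.34 on day 4 and 4.72 ± 1.23 on day 8, and 4.90 ± 1.64, 5.63 ± 1.45 and 3.50 ± 0.54 in endothelial cells on the same days.

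**Figure D1:**
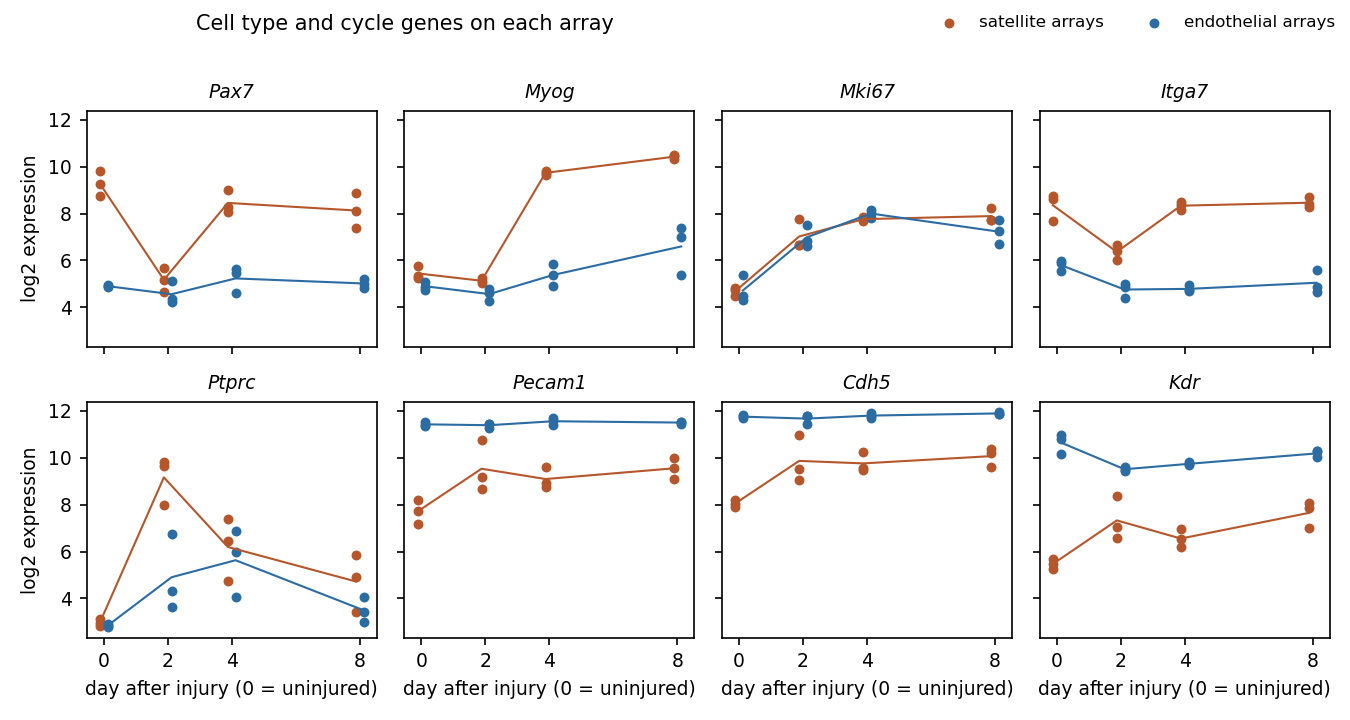
Log2 value of 8 marker genes on each array (points) and group means (lines) against days after injury, for satellite and endothelial cells, 3 arrays per group. Pax7 dips in satellite cells on day 2, Myog climbs there by days 4 and 8, and Ptprc is highest in satellite cells on day 2.

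Satellite and endothelial cells of uninjured muscle were compared to ask which transcripts set the resting populations apart. Satellite cells held more Chodl (6.41, SE 0.50, adjusted p = 7.01e-09), more Mrln, which encodes the calcium pump inhibitor myoregulin (5.07, SE 0.49, adjusted p = 1.17e-07), and more Chrdl2, a chordin-like BMP antagonist (5.06, SE 0.31, adjusted p = 3.81e-10). They held more Pax7 (4.37, SE 0.37, adjusted p = 1.92e-08) and more Fgfr4, an FGF receptor (4.96, SE 0.25), Sdc4 (4.81, SE 0.43) and Myod1 (2.17, SE 0.29). Endothelial cells held 36.5-fold more Kdr, the main VEGF receptor (-5.19, SE 0.35, adjusted p = 9.68e-10 for satellite minus endothelial), and more Ly6c1 (-5.90, SE 0.56), Car4 (-5.72, SE 0.66), Emcn (-5.18, SE 0.48), Pecam1 (-3.72, SE 0.38) and Cdh5 (-3.71, SE 0.33). Of 2393 called genes, 1067 were higher in satellite cells and 1326 in endothelial cells.

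By list, of 26 measured endothelial identity genes 0 were higher and 26 lower (0 and 26 adjusted over the list alone) in satellite cells. The median was -3.74 (camera adjusted p = 7.77e-29, adjusted p = 0.0448 with an estimated correlation). Of 20 quiescence genes 11 were higher and 3 lower (12 and 3 adjusted over the list alone). The median was 2.08 (camera adjusted p = 7.92e-08, adjusted p = 0.0448 with an estimated correlation). Of 20 fatty acid handling genes 2 were higher and 9 lower (2 and 9 adjusted over the list alone). The median was -0.87 (camera adjusted p = 0.00134, adjusted p = 0.0975 with an estimated correlation). Those lower in satellite cells included Fabp5, a fatty acid binding protein (-4.29, SE 0.50), and Gpihbp1, the endothelial anchor of lipoprotein lipase (-4.23, SE 0.34). Of 23 interferon response genes 0 were higher and 18 lower (0 and 20 adjusted over the list alone). The median was -2.35 (camera adjusted p = 4.31e-12, adjusted p = 0.109 with an estimated correlation). The mean over the interferon list was 8.76 on endothelial day 0 replicate 3 against 7.05 and 7.09 on replicates 1 and 2, and without replicate 3 its median difference was -1.56 (adjusted p = 6.55e-10).

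The day 0 satellite arrays also held genes known from other mononuclear muscle cells. The Sca1 gate should remove Sca1-positive fibro-adipogenic cells. Which other cells passed the alpha7-integrin gate was not tested. Dpt, a matrix protein of fibroblasts (6.35, SE 0.54, adjusted p = 1.73e-08), Dcn (5.09, SE 0.50), the smooth muscle gene Cnn1 (5.41, SE 0.55) and the chemokine gene Ccl19 (6.32, SE 0.95) were higher than in endothelial cells. Of 13 fibro-adipogenic progenitor markers 10 were higher and 0 lower (10 and 0 adjusted over the list alone). The median was 2.43 (camera adjusted p = 2.87e-10, adjusted p = 0.00423 with an estimated correlation). Of 14 pericyte and smooth muscle markers 11 were higher and 0 lower (11 and 0 adjusted over the list alone). The median was 2.03 (camera adjusted p = 4.11e-08, adjusted p = 0.109 with an estimated correlation). The mean over the pericyte and smooth muscle list was 9.35 ± 0.49 in satellite cells and 7.20 ± 0.36 in endothelial cells. Of 34 extracellular matrix genes 19 were higher and 0 lower (19 and 0 adjusted over the list alone). The median was 1.52 (camera adjusted p = 1.34e-10, adjusted p = 0.0975 with an estimated correlation).

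Satellite cells of day 2 were compared with day 0 to follow their exit from rest while the muscle degenerates. Pax7 fell by 4.10 on the log2 scale (SE 0.37, adjusted p = 6.8e-08), from 9.28 ± 0.52 to 5.17 ± 0.51. Chodl fell (-6.88, SE 0.50, adjusted p = 3.45e-09), and Mrln (-5.53, SE 0.49), Clmn (-5.14, SE 0.27), Chrdl2 (-5.04, SE 0.31) and Itga7 (-1.99, SE 0.28) fell as well. Mki67, a marker of dividing cells, rose (2.34, SE 0.33, adjusted p = 1.32e-05). Myod1 and Myog, the transcription factors of myoblasts and of differentiating myocytes, were not called (-0.78, SE 0.29, adjusted p = 0.0471 and -0.32, SE 0.34, adjusted p = 0.552). In all, 1528 genes rose and 1360 fell.

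Among the largest rises on day 2 were genes known from neutrophils, macrophages and inflammation. S100a8, a calprotectin subunit abundant in neutrophils, rose (8.71, SE 0.57, adjusted p = 6.14e-10), from 2.18 ± 0.13 to 10.89 ± 0.33. Its partner S100a9 (7.61, SE 0.52), the protease gene Ctss (7.73, SE 0.62), the cytokine gene Il1b (7.54, SE 0.64) and the neutrophil chemokine gene Cxcl2 (7.38, SE 0.52) rose too. Of 19 macrophage and leukocyte markers 19 rose and 0 fell (19 and 0 adjusted over the list alone), with Tyrobp (7.09, SE 0.61), Cd52 (7.10, SE 0.72) and Ptprc (6.20, SE 0.79, adjusted p = 4.71e-06). The median was 5.30 (camera adjusted p = 1.07e-18, adjusted p = 0.0931 with an estimated correlation). Of 24 inflammatory genes 17 rose and 1 fell (18 and 1 adjusted over the list alone), with Ptgs2 at 6.85 and Ccl2 at 6.54. The median was 2.30 (camera adjusted p = 1.15e-09, adjusted p = 0.00171 with an estimated correlation). Of 23 interferon response genes 20 rose and 0 fell (20 and 0 adjusted over the list alone), with Irf7 (4.22, SE 0.52) and Rsad2 (3.71, SE 0.40). The median was 2.68 (camera adjusted p = 6.71e-14, adjusted p = 0.0931 with an estimated correlation).

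Genes of rest and division moved in opposite directions on day 2, beside the leukocyte markers given above. The lower levels were not particular to genes of rest. Of 127 lineage genes, called at least 4-fold higher in satellite than in endothelial cells on days 0, 4 and 8, 122 were lower on day 2 (median -2.40). They were picked by level alone and include matrix genes such as Col6a1, so not all need come from satellite cells. Of 20 quiescence genes 1 rose and 16 fell (1 and 16 adjusted over the list alone), with Fgfr4 (-4.37, SE 0.25) and the growth signalling inhibitor Spry1 (-4.13, SE 0.44) among the falls. The median was -2.58 (camera adjusted p = 2.16e-13, adjusted p = 0.00643 with an estimated correlation). Of 38 cell cycle genes 31 rose and 0 fell (31 and 0 adjusted over the list alone), with Ccna2 (3.72, SE 0.32), Top2a (3.31, SE 0.31) and Cdk1 (3.24, SE 0.49). The median was 1.77 (camera adjusted p = 5.79e-18, adjusted p = 0.0707 with an estimated correlation). Of 30 myogenic differentiation genes 1 rose and 5 fell (1 and 5 adjusted over the list alone), and the list was not called (median 0.01, camera adjusted p = 0.712, mean -0.16, so median and mean differ in sign). Of 26 endothelial identity genes 16 rose and 0 fell (16 and 0 adjusted over the list alone), with Emcn at 2.90. The median was 1.36 (camera adjusted p = 5.64e-07, adjusted p = 0.308 with an estimated correlation). Pecam1 (1.83, SE 0.38), Cdh5 (1.82, SE 0.33) and Kdr (1.86, SE 0.35) rose as well. Of 14 pericyte and smooth muscle markers 0 rose and 14 fell (0 and 14 adjusted over the list alone). The median was -2.67 (camera adjusted p = 1.34e-10, adjusted p = 0.0931 with an estimated correlation). Of 13 fibro-adipogenic progenitor markers 2 rose and 9 fell (3 and 9 adjusted over the list alone). The median was -1.41 (camera adjusted p = 0.00286, adjusted p = 0.0931 with an estimated correlation). Day 2 satellite replicate 2 stood apart: its mean over the leukocyte list was 8.34 against 10.2 and 10.1 on the others, and over the endothelial list 8.16 against 6.35 and 6.64. Mki67 was at 7.78 on that replicate against 6.65 and 6.65.

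Satellite cells of day 4 were compared with day 0 to ask which programmes run while new fibres form. Myog rose 19.5-fold (4.29, SE 0.34, adjusted p = 2.19e-08), from 5.45 ± 0.28 to 9.74 ± 0.09, and Mymk, which encodes the myoblast fusion protein myomaker, rose (5.10, SE 0.35, adjusted p = 3.65e-09). Of 30 myogenic differentiation genes 18 rose and 2 fell (19 and 2 adjusted over the list alone), with Tnnt2, the troponin T of heart and embryonic muscle (5.08, SE 0.48), and Chrng, the foetal subunit of the acetylcholine receptor (4.33, SE 0.30). The median was 2.26 (camera adjusted p = 1.75e-14, adjusted p = 0.023 with an estimated correlation). Mki67 was above day 0 (3.08, SE 0.33, adjusted p = 1.19e-06), and of 38 cell cycle genes 33 rose and 0 fell (33 and 0 adjusted over the list alone). The median was 1.99 (camera adjusted p = 7.51e-30, adjusted p = 0.023 with an estimated correlation). Pax7 was at 8.46 ± 0.49 and was not called (-0.82, SE 0.37, adjusted p = 0.146). In all, 918 genes rose and 769 fell.

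Of 20 quiescence genes 1 rose and 7 fell (2 and 9 adjusted over the list alone) on day 4. The median was -0.77 (camera adjusted p = 1.65e-06, adjusted p = 0.0495 with an estimated correlation). The falls included Calcr, the calcitonin receptor of resting satellite cells (-2.63, SE 0.33), Chrdl2 (-4.83, SE 0.31) and Bmp4 (-3.58, SE 0.50), and Cdkn1c, a cell cycle inhibitor, rose (2.42, SE 0.26). Of 34 extracellular matrix genes 12 rose and 2 fell (13 and 2 adjusted over the list alone), with Timp1 at 4.88 and Vcan at 4.01. The median was 0.65 (camera adjusted p = 0.00905, adjusted p = 0.38 with an estimated correlation). Clmn (-4.89, SE 0.27), Ccl19 (-6.05, SE 0.95), Cnn1 (-4.82, SE 0.55) and Vtn (-4.64, SE 0.63) had large falls. Of 14 pericyte and smooth muscle markers 0 rose and 11 fell (0 and 13 adjusted over the list alone). The median was -2.35 (camera adjusted p = 6.37e-14, adjusted p = 0.0495 with an estimated correlation). Leukocyte genes stayed above day 0: Ctss (6.82, SE 0.62), Tyrobp (5.64, SE 0.61), Ms4a7 (5.30, SE 0.75) and the class II gene H2-Aa (5.23, SE 0.94) rose, as did Ptprc (3.23, SE 0.79), and of 19 leukocyte markers 17 rose and 0 fell (18 and 0 adjusted over the list alone). The median was 3.23 (camera adjusted p = 4.09e-15, adjusted p = 0.101 with an estimated correlation). Of 24 inflammatory genes 9 rose and 0 fell (9 and 0 adjusted over the list alone). The median was 1.02 (camera adjusted p = 0.000112, adjusted p = 0.0277 with an estimated correlation). Of 23 interferon genes 9 rose and 0 fell (11 and 0 adjusted over the list alone). The median was 1.07 (camera adjusted p = 2.67e-05, adjusted p = 0.333 with an estimated correlation). Of 26 endothelial identity genes 9 rose and 0 fell (12 and 0 adjusted over the list alone), with Cdh5 at 1.71. The median was 0.99 (camera adjusted p = 7.39e-05, adjusted p = 0.369 with an estimated correlation).

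Satellite cells of day 8 were compared with day 0 to ask what remains of the response as the muscle is rebuilt. Myog was 31.5-fold above day 0 (4.98, SE 0.34, adjusted p = 7.08e-09), at 10.42 ± 0.09, and Mymk was above it as well (5.35, SE 0.35, adjusted p = 4.02e-09). The cardiac and embryonic actin gene Actc1 (4.75, SE 0.55) and Tnnt2 (4.26, SE 0.48) rose, and of 30 myogenic differentiation genes 22 rose and 0 fell (22 and 0 adjusted over the list alone). The median was 2.32 (camera adjusted p = 9.16e-25, adjusted p = 0.00375 with an estimated correlation). Of 16 mature myofibre genes 11 rose and 0 fell (14 and 0 adjusted over the list alone), with Mylpf at 3.20 and Acta1 at 2.86. The median was 2.09 (camera adjusted p = 1.16e-10, adjusted p = 0.141 with an estimated correlation). The myofibre list averaged 6.96 on replicate 1 and 9.24 and 9.52 on replicates 2 and 3. In all, 616 genes rose and 281 fell.

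Dividing-cell transcripts stayed high on day 8. Mki67 was above day 0 (3.21, SE 0.33, adjusted p = 1.66e-06), and of 38 cell cycle genes 33 rose and 0 fell (33 and 0 adjusted over the list alone), with Ccna2 (4.05, SE 0.32) and Cdk1 (3.87, SE 0.49). The median was 1.75 (camera adjusted p = 6.89e-38, adjusted p = 0.00558 with an estimated correlation). Cdkn1c rose (3.00, SE 0.26), while of 20 quiescence genes 1 rose and 4 fell (1 and 7 adjusted over the list alone). The median was -0.61 (camera adjusted p = 0.000535, adjusted p = 0.153 with an estimated correlation). Pax7 was at 8.13 ± 0.73 (-1.15, SE 0.37, adjusted p = 0.06, not called, but called on leaving out satellite day 0 replicate 2, day 2 replicate 2 or day 8 replicate 1 or endothelial day 4 replicate 1, with adjusted p down to 0.0177). Of 34 extracellular matrix genes 9 rose and 1 fell (13 and 2 adjusted over the list alone), with Timp1 (3.62, SE 0.31) and Lum (3.09, SE 0.48). The median was 0.78 (camera adjusted p = 4.48e-08, adjusted p = 0.141 with an estimated correlation). Outside the list, the microfibril gene Mfap4 rose (4.42, SE 0.39). Clmn (-5.04, SE 0.27), Cldn1, a tight junction gene (-4.17, SE 0.23), Tnxb (-3.69, SE 0.23) and Chrdl2 (-3.40, SE 0.31) had the largest falls. Other cell types still showed: Ctss was at 5.39, and of 19 leukocyte markers 10 rose and 0 fell (15 and 0 adjusted over the list alone). The median was 2.20 (camera adjusted p = 6.65e-10, adjusted p = 0.186 with an estimated correlation). Among 26 endothelial identity genes 12 rose and 0 fell (14 and 0 adjusted over the list alone), with Kdr (2.18, SE 0.35), Cdh5 (2.02, SE 0.33) and Pecam1 (1.84, SE 0.38). The median was 1.23 (camera adjusted p = 1.16e-10, adjusted p = 0.186 with an estimated correlation). Of 14 pericyte and smooth muscle markers 0 rose and 4 fell (0 and 7 adjusted over the list alone). The median was -1.06 (camera adjusted p = 1.15e-05, adjusted p = 0.188 with an estimated correlation). Among 24 inflammatory genes 7 rose and 1 fell (9 and 1 adjusted over the list alone). The median was 0.50 (camera adjusted p = 0.0012, adjusted p = 0.0822 with an estimated correlation). Of 23 interferon genes 7 rose and 0 fell (9 and 0 adjusted over the list alone). The median was 0.90 (camera adjusted p = 9.88e-05, adjusted p = 0.297 with an estimated correlation).

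Endothelial cells of day 2 were compared with day 0 to ask how vessels respond while the fibres degenerate. Pgf, the placental growth factor gene, rose (4.96, SE 0.39, adjusted p = 1.35e-07), and Apln, the apelin gene and a marker of sprouting tip cells, rose 19.7-fold (4.30, SE 0.44, adjusted p = 3.29e-06). Myc rose 13.6-fold (3.76, SE 0.30, adjusted p = 1.59e-07) and the matrix protease gene Mmp14 11-fold (3.46, SE 0.31, adjusted p = 5.6e-07). Mki67 rose (2.27, SE 0.33, adjusted p = 0.000147), from 4.72 ± 0.57 to 6.99 ± 0.46. Among identity genes, Pecam1 was at 11.39 ± 0.09 and Cdh5 at 11.67 ± 0.19, neither called (-0.04, SE 0.38 and -0.08, SE 0.33). Kdr fell (-1.15, SE 0.35, adjusted p = 0.0415), a call lost on leaving out any 1 of endothelial day 0 replicates 1 and 2, the 3 arrays of day 2, day 4 replicates 2 and 3 and day 8 replicate 1, with values up to -0.98 and adjusted p up to 0.152. Flt1 fell too (-1.21, SE 0.32, adjusted p = 0.0193), a call lost without endothelial day 0 replicate 2 or 3 or day 2 replicate 1 or 2 (up to -1.13, adjusted p up to 0.0771). So did Itga7 (-1.05, SE 0.28, adjusted p = 0.0214), a call lost without day 0 replicate 1 or 2 or day 2 replicate 2 (up to -0.87, adjusted p up to 0.111). In all, 524 genes rose and 423 fell.

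Of 38 cell cycle genes 26 rose and 0 fell (28 and 0 adjusted over the list alone) in endothelial cells on day 2, with Top2a (3.57, SE 0.31) and Gins2 (3.05, SE 0.42). The median was 1.31 (camera adjusted p = 3.64e-27, adjusted p = 0.0155 with an estimated correlation). Of 23 ribosome biogenesis genes 8 rose and 0 fell (9 and 0 adjusted over the list alone), with Nop58 (1.64, SE 0.24) and Gar1 (1.41, SE 0.26) beside Myc. The median was 0.83 (camera adjusted p = 7.01e-13, adjusted p = 0.00598 with an estimated correlation). Of 25 sprouting genes 7 rose and 3 fell (8 and 3 adjusted over the list alone). The median was 0.39 (camera adjusted p = 0.00348, adjusted p = 0.332 with an estimated correlation). Of 34 extracellular matrix genes 9 rose and 0 fell (10 and 1 adjusted over the list alone), with Tnc at 3.67. The median was 0.12 (camera adjusted p = 0.00686, adjusted p = 0.383 with an estimated correlation). AA467197 (6.73, SE 0.39) was among the largest rises, and Timp4, a metalloproteinase inhibitor (-4.59, SE 0.54), Cdh23 (-3.59, SE 0.22), Ecm2 (-3.37, SE 0.43) and Aldh1l1 (-3.10, SE 0.30) were among the largest falls. Of 26 endothelial identity genes 0 rose and 3 fell (0 and 3 adjusted over the list alone). The median was -0.24 (camera adjusted p = 0.0297, adjusted p = 0.698 with an estimated correlation). This call was lost without endothelial day 0 replicate 2 (adjusted p = 0.0557) and without day 2 replicate 1 (adjusted p = 0.137).

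Leukocyte, pericyte and fibre transcripts also moved in the endothelial arrays of day 2. S100a8 (5.95, SE 0.57), Cxcl2 (5.69, SE 0.52), Ctss (5.25, SE 0.62) and Tyrobp (5.05, SE 0.61) rose, and of 19 leukocyte markers 9 rose and 0 fell (17 and 0 adjusted over the list alone). The median was 2.07 (camera adjusted p = 7.01e-13, adjusted p = 0.172 with an estimated correlation). Ptprc was not called (2.07, SE 0.79, adjusted p = 0.114). Of 24 inflammatory genes 9 rose and 0 fell (9 and 0 adjusted over the list alone), with Ccl2 (4.74, SE 0.41) and Il6 (3.15, SE 0.51). The median was 0.40 (camera adjusted p = 1.13e-06, adjusted p = 0.00598 with an estimated correlation). Of 23 interferon genes limma called 0 (0 adjusted over the list alone and 0 at an unadjusted p under 0.05, median 0.02, camera adjusted p = 0.784, mean -0.06, so median and mean differ in sign), while without endothelial day 0 replicate 3 the median was 0.54 (adjusted p = 0.00221). Among 14 pericyte and smooth muscle markers 0 rose and 5 fell (0 and 7 adjusted over the list alone), with Kcnj8 (-2.48, SE 0.50) and Rgs5 (-2.00, SE 0.43). The median was -1.07 (camera adjusted p = 1.97e-06, adjusted p = 0.172 with an estimated correlation). Vtn fell as well (-3.12, SE 0.63). Of 16 mature myofibre genes 0 rose and 8 fell (0 and 8 adjusted over the list alone). The median was -1.53 (camera adjusted p = 1.34e-08, adjusted p = 0.172 with an estimated correlation). Of 30 myogenic differentiation genes 0 rose and 7 fell (0 and 7 adjusted over the list alone). The median was -0.41 (camera adjusted p = 0.000216, adjusted p = 0.172 with an estimated correlation). Of 20 genes of the satellite cell quiescence list 0 rose and 3 fell (0 and 6 adjusted over the list alone). The median was -0.41 (camera adjusted p = 0.00194, adjusted p = 0.172 with an estimated correlation).

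Endothelial cells of day 4 were compared with day 0 to ask which programmes accompany vessel growth. Mki67 rose (3.28, SE 0.33, adjusted p = 2.2e-06), to 8.00 ± 0.17, and so did Top2a (4.40, SE 0.31, adjusted p = 1.67e-08). Of 38 cell cycle genes 24 rose and 0 fell (25 and 0 adjusted over the list alone). The median was 1.64 (camera adjusted p = 9.46e-34, adjusted p = 0.00939 with an estimated correlation). Of 34 extracellular matrix genes 13 rose and 0 fell (18 and 1 adjusted over the list alone), with Tnc (3.12, SE 0.38), Mmp14 (3.23, SE 0.31) and Col15a1 (2.96, SE 0.41). The median was 1.06 (camera adjusted p = 2.69e-16, adjusted p = 0.0332 with an estimated correlation). Of 24 inflammatory genes 14 rose and 0 fell (15 and 0 adjusted over the list alone), with Il6 (4.73, SE 0.51), Ccl2 (4.67, SE 0.41) and Sele, the E-selectin gene (3.72, SE 0.46). The median was 1.73 (camera adjusted p = 2.07e-17, adjusted p = 3.94e-05 with an estimated correlation). In the same arrays the mean over the leukocyte list was 7.16 ± 1.11 and over the fibro-adipogenic list 5.37 ± 0.25. In all, 438 genes rose and 312 fell.

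Of 25 sprouting genes 5 rose and 1 fell (8 and 1 adjusted over the list alone) on day 4, with Pgf at 3.22 and Apln at 2.18. The median was 0.40 (camera adjusted p = 0.0212, adjusted p = 0.497 with an estimated correlation). Without endothelial day 0 replicate 3 this call was lost (adjusted p = 0.0563). Of 31 secreted factors 8 rose and 1 fell (8 and 1 adjusted over the list alone), with Postn at 3.20. The median was 0.16 (camera adjusted p = 0.00106, adjusted p = 0.163 with an estimated correlation). Pecam1 (0.13, SE 0.38) and Cdh5 (0.05, SE 0.33) were not called. Of 26 endothelial identity genes 1 rose and 1 fell (1 and 1 adjusted over the list alone), camera adjusted p = 0.525. AA467197 (5.90, SE 0.39) and Myc (3.43, SE 0.30) rose, and Timp4 (-4.45, SE 0.54), Cdh23 (-3.90, SE 0.22), Steap4 (-3.56, SE 0.72) and Atp1b2 (-3.42, SE 0.72) fell. Itga7 fell (-1.02, SE 0.28, adjusted p = 0.0304), a call lost without endothelial day 0 replicate 1 or 2 or any 1 array of day 4 (up to -0.94, adjusted p up to 0.109). Beside these, leukocyte genes were high: Ptprc rose (2.79, SE 0.79, adjusted p = 0.0363), a call lost without any 1 array of endothelial day 0 or without day 4 replicate 1 or 2 (down to 2.17, adjusted p up to 0.195). Ctss (5.84, SE 0.62), Tyrobp (5.46, SE 0.61), Cxcl2 (5.15, SE 0.52) and Ms4a7 (5.12, SE 0.75) rose, and of 19 leukocyte markers 14 rose and 0 fell (17 and 0 adjusted over the list alone). The median was 2.79 (camera adjusted p = 1.36e-19, adjusted p = 0.0889 with an estimated correlation). Of 14 pericyte and smooth muscle markers 0 rose and 5 fell (0 and 8 adjusted over the list alone), with Rgs5 (-3.24, SE 0.43), Kcnj8 (-3.04, SE 0.50) and Abcc9 (-2.97, SE 0.51). The median was -1.31 (camera adjusted p = 4.92e-06, adjusted p = 0.225 with an estimated correlation). Vtn fell here too (-3.52, SE 0.63). Of 16 myofibre genes 0 rose and 2 fell (0 and 8 adjusted over the list alone). The median was -1.29 (camera adjusted p = 2.31e-06, adjusted p = 0.235 with an estimated correlation). Of 23 interferon genes limma called 0 (0 adjusted over the list alone and 1 at an unadjusted p under 0.05, median 0.24, camera adjusted p = 0.0844), and without endothelial day 0 replicate 3 the median was 0.75 (adjusted p = 1.7e-08).

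Endothelial cells of day 8 were compared with day 0 to ask which changes last. Top2a (3.78, SE 0.31, adjusted p = 4.39e-07) and Mki67 (2.51, SE 0.33, adjusted p = 0.00012), at 7.23 ± 0.50, were above day 0, and of 38 cell cycle genes 14 rose and 0 fell (18 and 0 adjusted over the list alone). The median was 0.98 (camera adjusted p = 7.06e-28, adjusted p = 0.0209 with an estimated correlation). Of 34 extracellular matrix genes 11 rose and 0 fell (16 and 0 adjusted over the list alone), with Postn (3.07, SE 0.43, adjusted p = 0.000269) and Col15a1 (2.96, SE 0.41). The median was 1.05 (camera adjusted p = 1.16e-17, adjusted p = 0.023 with an estimated correlation). Fibro-adipogenic progenitor markers, which include matrix genes, moved in the same arrays, from a mean of 4.89 ± 0.17 on day 0 to 5.52 ± 0.19. Of 13 such markers 2 rose and 0 fell (5 and 1 adjusted over the list alone). The median was 0.37 (camera adjusted p = 0.00475, adjusted p = 0.166 with an estimated correlation). Prnd (3.73, SE 0.40), the imprinted gene Mest (3.50, SE 0.42), AA467197 (3.62, SE 0.39) and Ctss (3.97, SE 0.62) rose, and Nts, the neurotensin gene, fell (-3.12, SE 0.57). Myog rose too (1.70, SE 0.34, adjusted p = 0.00811), to 6.60 ± 1.06, a call lost without endothelial day 8 replicate 2 (1.49, adjusted p = 0.0583) or replicate 3 (1.3, adjusted p = 0.0715). Of the same myogenic differentiation list Actc1 (2.28) and Tnnt1 (1.40) rose and Casq2 fell (-2.22). These calls were lost on leaving out any 1 of 4, 3 and 2 arrays. The list mean was 5.75 ± 0.19 on day 0 and 6.01 ± 0.17 on day 8. In all, 156 genes rose and 133 fell.

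Of 25 sprouting genes 4 rose and 0 fell (7 and 0 adjusted over the list alone) in endothelial cells on day 8, with Mmp14 (2.56, SE 0.31) and Nid2 (2.02, SE 0.32). The median was 0.30 (camera adjusted p = 0.00371, adjusted p = 0.396 with an estimated correlation). Among 24 inflammatory genes 6 rose and 0 fell (8 and 0 adjusted over the list alone), with Il6 (3.38, SE 0.51). The median was 0.57 (camera adjusted p = 1.89e-07, adjusted p = 0.00581 with an estimated correlation). Among 26 endothelial identity genes limma called 0 (0 adjusted over the list alone and 2 at an unadjusted p under 0.05), camera adjusted p = 0.923. Of 19 leukocyte markers 2 rose and 0 fell (4 and 0 adjusted over the list alone). The median was 1.18 (camera adjusted p = 1.13e-06, adjusted p = 0.345 with an estimated correlation). Among 14 pericyte and smooth muscle markers 0 rose and 4 fell (0 and 7 adjusted over the list alone), with Pdgfrb (-3.28, SE 0.65) and Abcc9 (-2.80, SE 0.51). The median was -1.0 (camera adjusted p = 1.6e-06, adjusted p = 0.263 with an estimated correlation). Of 23 interferon genes limma called 0 (0 adjusted over the list alone and 0 at an unadjusted p under 0.05, median -0.21, camera adjusted p = 0.473). That list was called on leaving out endothelial day 0 replicate 1 (median -0.45, adjusted p = 0.01), replicate 2 (-0.44, adjusted p = 0.011) or replicate 3 (0.30, adjusted p = 0.00199), so its direction turned with the array left out. The count of 289 called genes depended on single arrays: it was 182 without endothelial day 0 replicate 1, 175 without day 0 replicate 2, 180 without day 8 replicate 2 and 162 without day 8 replicate 3. With array weights it was 459, which held 283 of the 289.

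**Figure D2:**
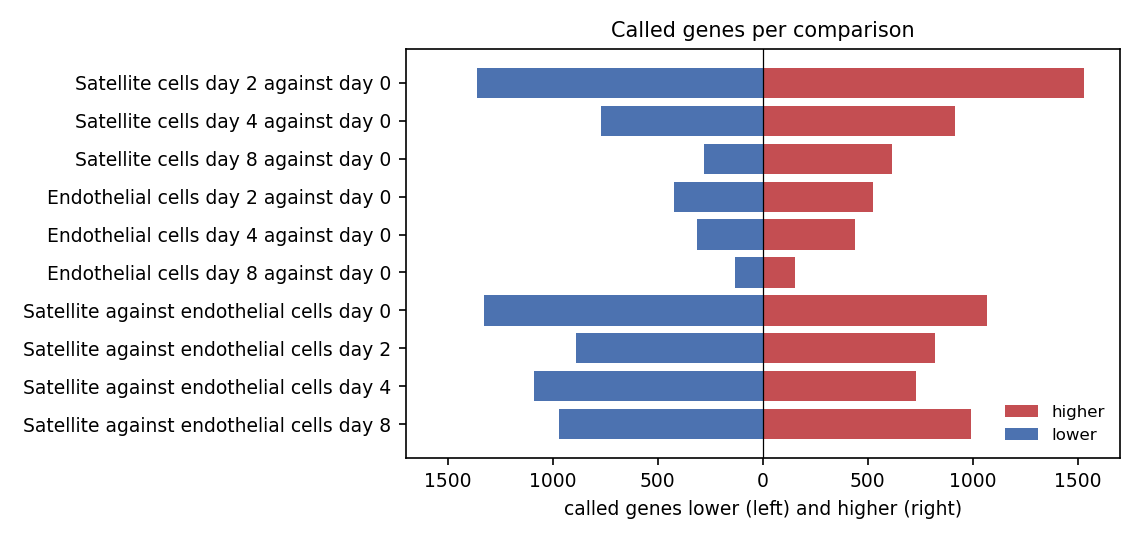
Number of genes called higher (bars to the right) and lower (bars to the left) in each comparison of a later day with day 0 and of satellite with endothelial cells, 3 arrays per group. Satellite cells on day 2 have the most, 1528 higher and 1360 lower, and endothelial cells on day 8 the fewest, 156 and 133.

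The cell types were also compared on each day after injury, to ask how far apart they stayed. On day 2, 819 genes were higher in satellite and 887 in endothelial cells, 732 and 1087 on day 4, and 991 and 968 on day 8. Pax7 was not called on day 2 (0.62, SE 0.37, adjusted p = 0.322) and was higher in satellite cells on day 4 (3.22, SE 0.37, adjusted p = 2.85e-06) and day 8 (3.11, SE 0.37, adjusted p = 4.25e-06). Myog was higher in satellite cells on day 4 (4.36, SE 0.34, adjusted p = 1.93e-08) and day 8 (3.83, SE 0.34, adjusted p = 1.16e-07) but was not called on day 2 (0.57, SE 0.34). Pecam1 was lower in satellite cells on day 2 (-1.86, SE 0.38, adjusted p = 0.0015), day 4 (-2.47, SE 0.38, adjusted p = 6.09e-05) and day 8 (-1.95, SE 0.38, adjusted p = 0.000675). Of 26 endothelial identity genes 0 were higher and 25 lower (0 and 25 adjusted over the list alone) in satellite cells on day 2. The median was -2.13 (camera adjusted p = 2.77e-20, adjusted p = 0.0739 with an estimated correlation). On day 4, 0 were higher and 26 lower (0 and 26 adjusted over the list alone). The median was -2.82 (camera adjusted p = 3.9e-27, adjusted p = 0.038 with an estimated correlation). On day 8, 0 were higher and 26 lower (0 and 26 adjusted over the list alone). The median was -2.46 (camera adjusted p = 4.45e-23, adjusted p = 0.0528 with an estimated correlation). Ptprc was higher in satellite than in endothelial cells on day 2 (4.26, SE 0.79, adjusted p = 0.000726).

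The response itself was compared between the cell types by the interaction contrast, in which a positive value is a greater rise or lesser fall in satellite cells. On day 2 it called 1614 genes, 906 positive and 708 negative, 596 (281 and 315) on day 4 and 310 (196 and 114) on day 8. Pax7 was negative on day 2 (-3.76, SE 0.53, adjusted p = 8.45e-05), as were Chodl (-5.76, SE 0.71) and Fgfr4 (-4.08, SE 0.35). These values come mostly from the satellite falls (-4.10, -6.88 and -4.37). In endothelial cells the genes were already low on day 0, at 4.90 ± 0.04, 4.14 ± 0.52 and 3.70 ± 0.28 (array medians 4.11 to 4.40), where a fall can be understated. Their endothelial means were still lower on day 2, most for Chodl, so each value is smaller in size than the satellite fall. Myc (-4.12, SE 0.43) and Mmp14 (-3.69, SE 0.44) were negative on day 2, with rises in endothelial cells. Mymk was positive on day 4 (4.45, SE 0.50, adjusted p = 1.09e-05) and day 8 (4.03, SE 0.50, adjusted p = 8.95e-05), and so was Myog (3.81, SE 0.49 and 3.28, SE 0.49). Kdr was positive on day 2 (3.01, SE 0.49, adjusted p = 0.000416), day 4 (2.00, SE 0.49, adjusted p = 0.02) and day 8 (2.65, SE 0.49, adjusted p = 0.0045), and its day 4 call was lost without endothelial day 0 replicate 2 (1.84, adjusted p = 0.0621) or satellite day 4 replicate 1 (1.81, adjusted p = 0.0533). Its endothelial means were lower after injury, and Pecam1 and Cdh5 rose beside it in satellite arrays. On day 2 satellite Kdr was at 8.37 on replicate 2, the array highest for the endothelial list, against 6.58 and 7.04. Endothelial RNA in the satellite sort was thus not told apart from a rise within satellite cells. Mki67 was not called on day 2 (0.07, SE 0.46, adjusted p = 0.956), day 4 (-0.21, SE 0.46, adjusted p = 0.901) or day 8 (0.70, SE 0.46, adjusted p = 0.518). The day 8 count of 310 was 200 without satellite day 8 replicate 3 and 183 without endothelial day 8 replicate 3, and with array weights the counts were 2443, 1047 and 512 on days 2, 4 and 8.

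By list, of 20 quiescence genes 0 were higher and 12 lower (1 and 14 adjusted over the list alone) in the interaction on day 2. The median was -1.83 (camera adjusted p = 8.37e-10, adjusted p = 0.0327 with an estimated correlation). In uninjured muscle 19 of the 20 were at least 1 above the array median in satellite cells and 12 in endothelial cells, so a fall of the others there can be understated. Of 30 myogenic differentiation genes 15 were higher and 0 lower (20 and 0 adjusted over the list alone) on day 4. The median was 2.01 (camera adjusted p = 3.81e-18, adjusted p = 0.0155 with an estimated correlation). On day 8, 11 were higher and 0 lower (19 and 0 adjusted over the list alone). The median was 1.97 (camera adjusted p = 3.34e-19, adjusted p = 0.012 with an estimated correlation). Of 24 inflammatory genes 10 were higher and 3 lower (13 and 3 adjusted over the list alone) on day 2. The median was 1.75 (camera adjusted p = 0.000104, adjusted p = 0.0327 with an estimated correlation). Of 19 leukocyte markers 11 were higher and 0 lower (19 and 0 adjusted over the list alone). The median was 2.92 (camera adjusted p = 8.37e-10, adjusted p = 0.271 with an estimated correlation). Of 23 interferon genes 16 were higher and 0 lower (20 and 0 adjusted over the list alone) on day 2. The median was 2.50 (camera adjusted p = 3.4e-16, adjusted p = 0.134 with an estimated correlation). Without endothelial day 0 replicate 3 it was 2.11. Of 38 cell cycle genes 2 were higher and 0 lower (2 and 0 adjusted over the list alone) on day 2. The median was 0.18 (camera adjusted p = 0.134). It was called without endothelial day 2 replicate 2 (median 0.35, adjusted p = 0.0104) and without satellite day 2 replicate 1 (0.35, adjusted p = 0.0171) or replicate 3 (0.30, adjusted p = 0.0309). On day 4, 1 were higher and 0 lower (4 and 0 adjusted over the list alone). The median was 0.34 (camera adjusted p = 0.0226, adjusted p = 0.521 with an estimated correlation), a call lost without endothelial day 4 replicate 3 (adjusted p = 0.217). On day 8, 2 were higher and 0 lower (4 and 0 adjusted over the list alone). They were Rrm2 and Mcm6, each with a call lost on leaving out any 1 of 8 arrays (adjusted p up to 0.102 and 0.078). The median of the list was 0.72 (camera adjusted p = 8.04e-07, adjusted p = 0.294 with an estimated correlation).

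The responses of the cell types, which share no arrays, also overlapped. On day 2, 235 genes rose in both (56.9 expected if independent), 151 fell in both (40.9 expected) and 29 moved in opposite directions (96.6 expected). On day 4 these numbers were 226, 94 and 18 (28.6, 17.1 and 44.3 expected), and on day 8 they were 84, 19 and 4 (6.83, 2.66 and 8.94 expected). Array order followed the days in both cell types, a shared preparation is not excluded, and leukocyte genes rose in both. These were not separated from a common response of the cells, and each could add to the overlap. Across genes, which are not independent replicates, the log2 differences correlated at 0.461, 0.475 and 0.293 on the 3 days. Genes that rose in both included 24, 23 and 14 of the cell cycle list and 9, 14 and 2 of the leukocyte list on days 2, 4 and 8. Over the whole course 3360 genes changed in satellite cells and 978 in endothelial cells by the F-test. Without the 3 satellite arrays of day 2, an alternative chosen after the data had been seen, the satellite count over days 4 and 8 was 1863, of which 1813 were shared.

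**Figure D3:**
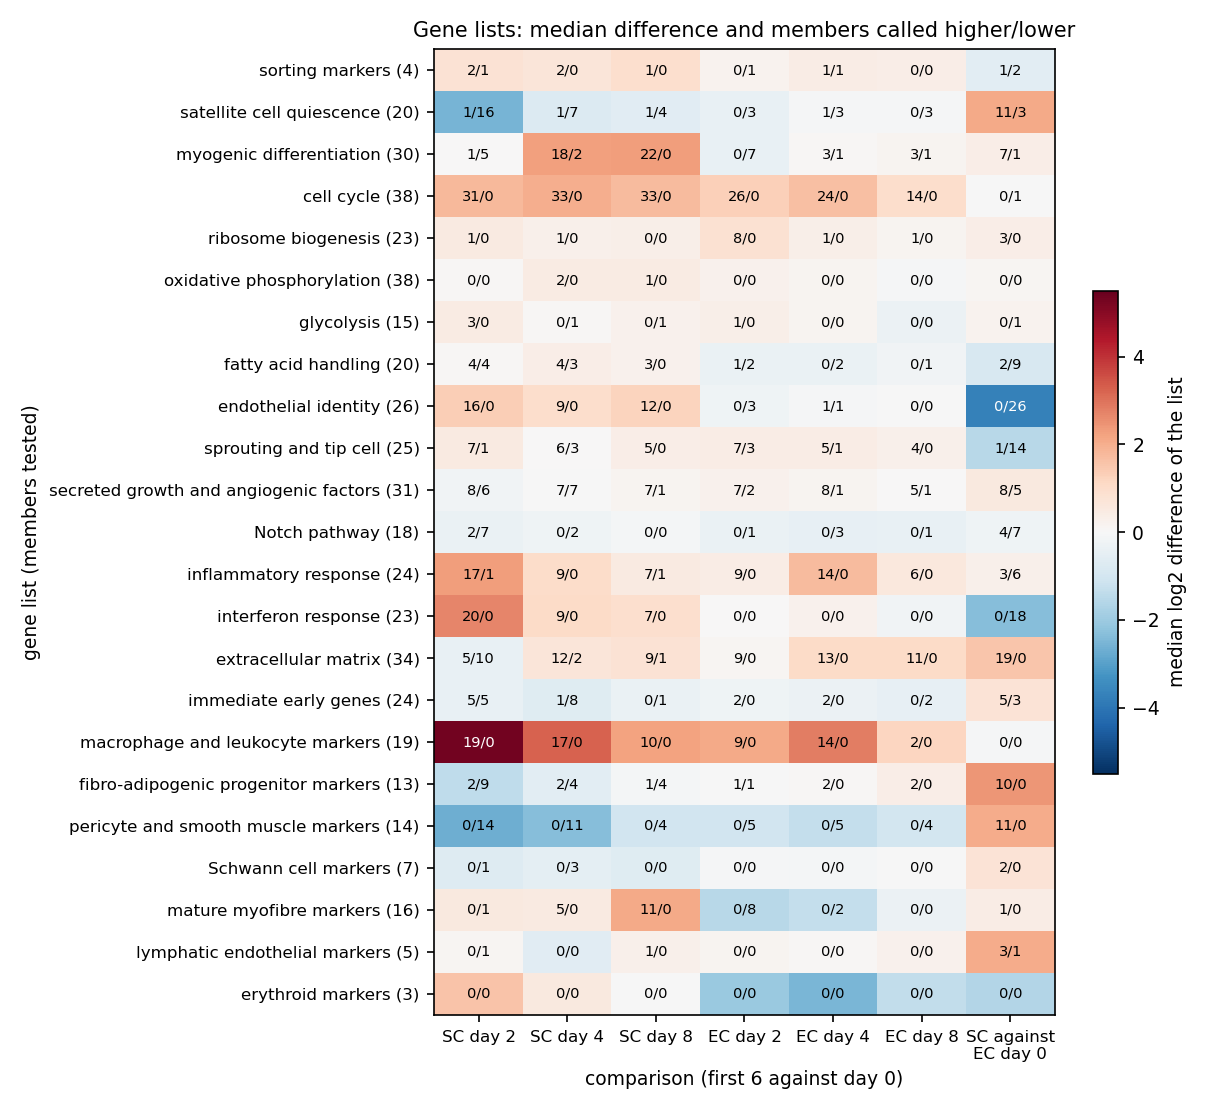
Median log2 difference of each of the 23 gene lists (colour) with the numbers of members called higher and lower (text in each cell), in the 6 comparisons with day 0 and in satellite against endothelial cells on day 0 (SC, satellite cells; EC, endothelial cells; 3 arrays per group). The leukocyte list has the highest median, 5.30 in satellite cells on day 2, and the endothelial identity list the lowest, -3.74 in satellite against endothelial cells on day 0.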

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

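Each test in this part was written down before its own result was seen, although the patterns were noticed in the same data. The rules for reading the tests of dilution, of mural cell RNA, of the interferon starting level and of the interaction splits were made stricter after their values were seen. The results here stand out because the interaction test called differences in the response to injury between the cell types. It called 1614 genes on day 2, 596 on day 4 and 310 on day 8. Values are satellite minus endothelial differences of the log2 responses.

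On day 2 the 4 highest were the purine enzyme genes Gda (5.66, SE 0.37) and Xdh (5.46, SE 0.62), the lymphoid gene Slfn2 (5.53, SE 0.67) and the monocyte surface gene Ly6c2 (5.46, SE 0.48), and the 4 lowest were Chodl (-5.76, SE 0.71), Dpt (-5.48, SE 0.76), Chrdl2 (-5.08, SE 0.44) and Mrln (-4.91, SE 0.70). On day 4 they were Cdkn1c (4.46, SE 0.37), Mymk (4.45, SE 0.50), Ociad2 (4.17, SE 0.69) and the titin gene Ttn (3.88, SE 0.43), and at the low end Ccl19 (-7.60, SE 1.34), Cnn1 (-5.14, SE 0.78), Chrdl2 (-4.90, SE 0.44) and Fjx1 (-4.77, SE 0.73). On day 8 they were Cdkn1c (4.44, SE 0.37), Ctla2a (4.21, SE 0.88), Mymk (4.03, SE 0.50) and the myotilin gene Myot (3.68, SE 0.92), and at the low end Cldn1 (-4.22, SE 0.32), Tnxb (-3.68, SE 0.32), Clmn (-3.63, SE 0.38) and Mfap5 (-3.61, SE 0.78). The genes at the low end stood low in endothelial cells on day 0, between 3.29 ± 0.05 (Cldn1) and 4.90 ± 0.04 (Fjx1) against array medians of 4.11 to 4.40. A fall there can be understated. The satellite falls of Chodl and Mrln on day 2 and of Clmn on day 8 were larger than these differences. Their endothelial means were therefore lower than on day 0 as well. For Ccl19 on day 4 the difference was larger than the satellite fall, so its endothelial mean was higher. The Myot call was lost on leaving out any 1 of the 6 arrays of day 0, the 3 endothelial arrays of day 8 and satellite day 8 replicates 2 and 3, with values down to 3.03 and adjusted p up to 0.105. Among the lists, quiescence on day 2 (median -1.83), inflammatory response on day 2 (1.75) and myogenic differentiation on day 4 (2.01) and day 8 (1.97) were called in the interaction also with an estimated correlation (adjusted p = 0.0327, 0.0327, 0.0155 and 0.012).

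Splits of the arrays into other groups were counted for each comparison. For the interactions 4, 4 and 2 of 100 splits called as many genes as the real ones (1614, 596 and 310) on days 2, 4 and 8, the real split included, and the highest other counts were 2220, 956 and 414. Most of the 100 break the satellite response itself, so these shares do not show whether chance can be excluded for its difference from the endothelial response. Of the 9 other splits that kept the satellite arrays by day and mixed the endothelial arrays, 3, 3 and 1 were as large. These splits keep the satellite response in the contrast, so large counts follow from it. They cannot show what lies behind the real counts. The 9 others that kept the endothelial arrays by day called at most 247, 269 and 52 genes, and those that kept neither at most 2. For genes that changed over time, 1 of 100 splits, the real one, gave 3360 in satellite cells (highest other 1497) and 1 of 100 gave 978 in endothelial cells (highest other 538). A random grouping of the arrays is thus argued against, at a share under 0.05 of the splits drawn. Array order follows the days, so the splits do not separate it from day. Each comparison of 2 groups has 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, called as many genes in each. The highest other counts were 128, 3 and 5 against 2888, 1687 and 897 in satellite cells on days 2, 4 and 8, and 0, 1 and 1 against 947, 750 and 289 in endothelial cells. In satellite against endothelial cells they were 0, 325, 1 and 0 against 2393, 1706, 1819 and 1959 on days 0, 2, 4 and 8.

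On day 2 the satellite arrays showed low levels of satellite genes beside high levels of leukocyte genes, whose most abundant members reached 11.42 ± 0.89 (Laptm5) and 11.11 ± 0.47 (Tyrobp). An exchange of satellite and endothelial arrays is argued against, because the median of 127 lineage genes, called at least 4-fold higher in satellite than in endothelial cells on days 0, 4 and 8, was higher in the satellite array in all 9 pairs of day 2 arrays (lowest median difference 0.66). Of the 127, 5 belong to the pericyte and smooth muscle or fibro-adipogenic lists. Others, such as Col1a2, Col6a1 and Loxl1, are matrix genes, and how many of the 127 come from other cells was not tested. Dilution of the satellite RNA by RNA of leukocytes and endothelial cells that passed the CD45 and CD31 gates stays open: 96.1% of the lineage genes were lower on day 2 (median -2.40), but this restates the pattern and would follow from real falls or from fewer mural and fibro-adipogenic cells too. Of 19 leukocyte markers 1 was well above the array median in resting satellite cells and 1 is held by another list, while the endothelial markers include 17 of 26 with such levels on day 0. Whether Pax7 and other genes fell beyond a common dilution stays open, since lineage genes also lower on day 4 differed from the others by -0.59 and both groups were low, and the real response of satellite cells to injury was not separated from it.

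In endothelial arrays pericyte genes were lower on all 3 days after injury, with medians of -2.00, -2.80 and -2.26 over 7 genes (Rgs5 from 11.46 ± 0.17 to 8.22 ± 0.90 on day 4). A loss of RNA of all mural cells, smooth muscle included, stays open: 7 contractile genes had a median of -0.40 over the 3 days (SD 0.70 between genes) against -2.19 for the pericyte genes, with 7, 4 and 4 of them lower on days 2, 4 and 8 (medians -0.56, -0.40 and -0.26), of which limma called 1, Myh11 on day 4 (named after its value was seen). Less pericyte RNA in the sort, which the CD31 gate should remove, stays open as well. Across replicates within groups the 7 genes moved together (mean correlation 0.490, at percentile 99.99 of 10000 random lists), as the prediction required. The test took deviations from group means, and its random lists were matched only on expression. It therefore shows that these genes vary together between arrays of a group, and cannot show a loss after injury. Of the 14 pericyte and smooth muscle markers 12 were well above the array median in uninjured endothelial cells, 2 are held by another list, and a change of transcription within the cells was not tested.

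Interferon genes were higher in day 2 than in day 0 satellite arrays (camera adjusted p = 6.71e-14, adjusted p = 0.0931 with an estimated correlation), while the list was not called in endothelial arrays. Leukocyte RNA is a candidate source that the CD45 gate should remove, and it stays open: within days the interferon and leukocyte levels of 9 satellite arrays correlated at 0.325 (one-sided exact permutation p = 0.208, rho 0.367 with p = 0.185). The correlation was 0.636 without the 2 arrays whose leukocyte deviation lay farthest from the median, replicate 2 of day 2 and of day 8. That value kept the day means of all 9 arrays, so it is not a correlation within days and decides nothing. The rule written down named only the first correlation and its permutation p. A high starting level in endothelial cells also stays open, since the median gene was higher in their day 0 arrays than in day 2 satellite arrays by 0.045 (SE of array medians 0.66) and the mean lower by 0.21 (SE 0.59), while the median gene was 2.43 above day 0 satellite arrays. That level rests partly on endothelial day 0 replicate 3, which stood at 8.76 against 7.05 and 7.09, and without it the endothelial list was called on day 2 (median 0.54, adjusted p = 0.00221) and day 4 (median 0.75, adjusted p = 1.7e-08). Of the 23 genes 21 were well above the array median in uninjured endothelial cells and 12 in uninjured satellite cells.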

How the results depend on the processing

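The alternative without the 3 satellite arrays of day 2 was chosen only after the results were seen, and the other alternatives were planned. Of 637 gene results 509 stayed on the same side of the threshold under each alternative run. None (0) turned direction where the gene was called in the main fit or in the alternative. Changes of sign in genes called in neither were not counted. Of 299 list results 122 stayed on the same side, with 137 losing their call under an estimated correlation and 27 losing and 18 gaining one under fry. All 15 counts stayed within 1.5 times their value under centring, quantile normalization within cell types, either filter, the mean of probe sets, trend and robust moderation, no minimum difference and the replicate block, which gave 2919 genes for satellite day 2 and 293 for endothelial day 8. So did the counts run with only the 12 arrays of a cell type or with the random block.

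With array weights, in which satellite day 2 replicate 2 had the lowest weight (0.311), endothelial day 8 called 459 genes and the interactions 2443, 1047 and 512 on days 2, 4 and 8. Without the 3 satellite arrays of day 2 the satellite F-test called 1863 genes, with 1 comparison fewer to draw on. The cause of the weighted counts was not tested.

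Leaving out each array in turn gave 162 to 361 genes for endothelial day 8 and 183 to 391 for the day 8 interaction, each with fewer arrays. For the other counts the range stayed within 1.5 times. Satellite day 2 ranged from 2558 to 3262, day 4 from 1557 to 1786 and day 8 from 700 to 970, endothelial day 2 from 674 to 1050 and day 4 from 553 to 860, and the interactions from 1164 to 2271 on day 2 and 437 to 739 on day 4. The random block by array name had a correlation of 0.0483 and was run for the 246 gene results that compare the cell types or their responses, of which none changed its call. How far rises and falls of genes near the array background are understated was not tested.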

Other observations

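No test in this part was chosen after its result was seen. The metabolic lists were followed beside the leukocyte and pericyte shifts described for the same arrays. Over all genes 20.5% were called in satellite cells on day 2. Of 38 oxidative phosphorylation genes 2 rose and 0 fell (2 and 0 adjusted over the list alone) in satellite cells on day 4. Of the 2, Uqcrc1 (1.19) lost its call on leaving out 1 array (0.87). The median of the list was 0.45 (camera adjusted p = 3.23e-05, adjusted p = 0.217 with an estimated correlation). On day 8, 1 rose and 0 fell (1 and 0 adjusted over the list alone). It was Uqcrq (1.01), a call lost on leaving out any 1 of 3 arrays (down to 0.92). The median of the list was 0.46 (camera adjusted p = 4.48e-08, adjusted p = 0.141 with an estimated correlation). Limma called 0 in satellite cells on day 2 and 0 in endothelial cells on days 2, 4 and 8 (7, 8, 5 and 6 at an unadjusted p under 0.05). In endothelial cells on day 2 the list was nevertheless called (median 0.25, camera adjusted p = 0.00319, adjusted p = 0.33 with an estimated correlation). Of 15 glycolysis genes 3 rose and 0 fell (3 and 0 adjusted over the list alone) in satellite cells on day 2. They were the lactate transporter gene Slc16a3 (2.29, SE 0.37), the hexokinase gene Hk2 (1.95, SE 0.28) and Pfkfb3, whose call was lost without satellite day 2 replicate 3 (1.92, SE 0.54, and 1.71 without it, adjusted p = 0.0506). The median was 0.43 (camera adjusted p = 0.0485, adjusted p = 0.202 with an estimated correlation). This list call was lost on leaving out any 1 of the 3 satellite arrays of day 0, satellite day 2 replicates 1 and 3, day 4 replicate 2 and day 8 replicates 2 and 3 and the 3 endothelial arrays of day 8 (adjusted p up to 0.0848). Of 20 fatty acid handling genes 4 rose and 4 fell (4 and 4 adjusted over the list alone) in satellite cells on day 2, camera adjusted p = 0.823, with Fabp5 at 4.17, and in endothelial cells, 1 rose and 2 fell (1 and 5 adjusted over the list alone), camera adjusted p = 0.0501, with Lpl at -2.28. The endothelial list was called without day 2 replicate 3 (adjusted p = 0.0105). It was also called without endothelial day 0 replicate 1 or any 1 of satellite day 0 replicates 1 and 3, day 2 replicates 1 and 2, day 4 replicates 1 and 3 and day 8 replicates 1 and 2 (adjusted p 0.043 to 0.0498). Of 23 ribosome biogenesis genes 1 rose and 0 fell (1 and 0 adjusted over the list alone) in satellite cells on day 2. It was Pes1 (1.13), a call lost on leaving out any 1 of 2 arrays (down to 0.86, adjusted p up to 0.0531). The median of the list was 0.49 (camera adjusted p = 0.00839, adjusted p = 0.202 with an estimated correlation).

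Notch pathway genes in satellite cells on day 2 included falls of Heyl (-3.55, SE 0.36), Hes1 (-2.67, SE 0.36), Notch3 (-2.63, SE 0.45) and Hey1 (-2.48, SE 0.36): of 18 members 2 rose and 7 fell (2 and 7 adjusted over the list alone). The median was -0.35 (camera adjusted p = 0.0499, adjusted p = 0.278 with an estimated correlation). The list call was lost on leaving out any 1 of the 3 satellite arrays of day 0, satellite day 2 replicates 1 and 3, the 3 of day 4 and day 8 replicates 2 and 3, or of endothelial day 0 replicate 2, day 2 replicates 2 and 3 and the 3 of day 8 (median down to -0.52, adjusted p up to 0.0848). Heyl and Notch3 are also mural cell genes and are among the 127 lineage genes whose lower level on day 2 is open to dilution, and the pericyte and smooth muscle list was lower in the same arrays (median -2.67). In endothelial cells on day 4, where that list was lower too (median -1.31), 0 rose and 3 fell (0 and 4 adjusted over the list alone), with Heyl at -2.44. The median was -0.43 (camera adjusted p = 0.00831, adjusted p = 0.163 with an estimated correlation). Of 31 secreted factors 8 rose and 6 fell (8 and 7 adjusted over the list alone) in satellite cells on day 2, where the list was not called (median -0.19, mean 0.24, which differ in sign), and 7 rose and 2 fell (9 and 2 adjusted over the list alone) in endothelial cells, with Bmp2 at 3.61. The median was 0.24 (camera adjusted p = 0.00116, adjusted p = 0.172 with an estimated correlation). Of 24 immediate early genes 1 rose and 8 fell (1 and 8 adjusted over the list alone) in satellite cells on day 4. The median was -0.68 (camera adjusted p = 3.23e-05, adjusted p = 0.237 with an estimated correlation).

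Markers of further cell types moved as follows. Of 7 Schwann cell markers 0 rose and 3 fell (0 and 3 adjusted over the list alone) in satellite cells on day 4. The median was -0.55 (camera adjusted p = 0.000546, adjusted p = 0.0684 with an estimated correlation). Of 5 lymphatic markers Prox1 alone fell in satellite cells on day 2 (-3.82, SE 0.32, adjusted p = 2.83e-08; 0 and 1 adjusted over the list alone). Prox1 is also among the 127 lineage genes, so this fall is open to dilution too. That list was not called (median 0.09, mean -0.54, which differ in sign). Of 3 erythroid markers limma called 0 in each comparison with day 0, with endothelial medians of -2.02, -2.49 and -1.36 on days 2, 4 and 8, of which 2, 2 and 0 fell adjusted over the list alone and 2, 2 and 1 had an unadjusted p under 0.05. Camera called this list on the 3 days (adjusted p = 0.0315, 0.0276 and 0.0488; adjusted p = 0.261, 0.24 and 0.345 with an estimated correlation). Without endothelial day 0 replicate 1 these calls were lost (adjusted p = 0.0944, 0.0942 and 0.148), as they were without day 2 replicate 2 on day 2, without day 4 replicate 2 or 3 on day 4. On day 8 the call was also lost without endothelial day 0 replicate 3, day 4 replicate 3 or day 8 replicate 1 or 2, or without satellite day 0 replicate 1, day 2 replicate 2 or any 1 array of day 8 (adjusted p up to 0.121). Of 4 sorting marker genes 2 rose and 1 fell (2 and 1 adjusted over the list alone) in satellite cells on day 2, camera adjusted p = 0.587. They were Ptprc, Pecam1 and Itga7, with values given above, and Cd34 was not called (-0.27, SE 0.37, adjusted p = 0.651). Of 13 fibro-adipogenic progenitor markers 2 rose and 0 fell (4 and 1 adjusted over the list alone) in endothelial cells on day 4, camera adjusted p = 0.0739. This list was called without endothelial day 0 replicate 1 (adjusted p = 0.0269) or day 4 replicate 2 (adjusted p = 0.0271).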
